A study of Caenorhabditis elegans with 4 samples.

How the data were processed

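Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites at the L4 larval stage. The series title writes GEI-1, whereas the strain, genotype and sample titles give gei-11; GEI-11 is used here. The strain carried an integrated transgene that expresses GEI-11 fused to TY1, EGFP and 3xFLAG tags, together with an unc-119 rescue marker. Per the labels' protocols, worms were grown in liquid culture at 20 °C on E. coli HB101, staged by developmental milestones, crosslinked with 2% formaldehyde and sonicated. Chromatin was precipitated with an affinity-purified goat antibody against GFP, and Illumina libraries were made after size selection on a gel. The 4 samples are 2 ChIP libraries and 2 input libraries, numbered as replicates 1 and 2 in both groups and labelled as separate extractions.

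The authors deposited 1 combined peak list for the series, and all values used here come from it. Per the file headers, positions are on the WormBase WS180 genome build. The source column of the deposited file names PeakSeq, a peak caller that compares ChIP reads with control reads, with no version. Each peak has a chromosome, a first and a last base, and a q-value (a p-value corrected for multiple testing) from the authors' peak caller. The attribute of each of the 687 deposited peaks repeats the same q-value. The aligner, the read filters, the q threshold and the way in which the replicates were combined are not given in the sources used here. The list gives no read numbers, fold enrichments or values per replicate, so the sequencing depth behind each peak is unknown and the spread between replicates could not be estimated. A q-value depends on depth and on the width of the region as well as on enrichment. It was therefore used only within this list, as −log10 q, to rank and filter peaks and to compare medians between groups of peaks.

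Analyses were run in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. A peak was placed by its midpoint. The list gives no chromosome lengths, and no WS180 genome or annotation was used here. The stretch of each chromosome from its first base to the end of its last peak, called its span, therefore stood for its length. This choice was made after the list had been seen. The design written before the data were examined foresaw no test of peaks per chromosome in that case, so this test is an addition.

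Peaks per chromosome were compared with each chromosome's share of the summed span by exact two-sided binomial tests with Benjamini-Hochberg adjustment over the 6 chromosomes. The share of autosomal peaks in the central 50% of the span was tested against 50% in the same way. The piRNA gene domains of chromosome IV were set, before the data were examined, as the 500 kb bins 10 to 14 and 28 to 34, which are 4.5 to 7 Mb and 13.5 to 17 Mb. Median −log10 q and median width inside and outside these domains were compared by two-sided permutation tests with 100000 resamples, with a 95% percentile interval from 2000 bootstrap draws. Clustering was tested by 1000 random placements of the peaks on their own chromosome. Shares are given with exact Clopper-Pearson 95% intervals, which treat peaks as independent and cover counting error only. The exact binomial and Fisher's exact tests also treat peaks as independent, so their p-values can be too small where peaks cluster. The same holds for the permutation tests of medians and of the central share of the autosomes. Counts in 1 Mb windows and in the last 25% of each span, the separate tests of the left and the right piRNA domain, the permutation test of a difference between the autosomes in their central share, the comparison of X with the autosomes within 10 and 20 width groups, and the split of peaks at a q of 1e-10, were added after the data had been seen. The random placement of each peak within its own 1 Mb window was also not planned.

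Alternatives were the 343 peaks with the lowest q, merging of peaks less than 1 kb apart (650 remained), occupied 50 kb bins in place of peaks, a central 33.3% of the autosomes, wider piRNA bins, 10000 rotations of the peaks round chromosome IV, comparison within chromosome IV and a neighbour distance of 20 kb in place of 5 kb. The number of genes per chromosome was taken from a RefSeq gene table on the WBcel235 assembly, of which only names, classes and chromosomes were used. Its coordinates were not compared with the WS180 peaks, so no peak was assigned to a gene, exon, intron or UTR. The planned comparisons of peaks with annotated genes, gene lists and sequence motifs were therefore not run.

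The tests were checked on simulated lists of 687 peaks, each placed independently of the others. The deposited peaks clustered, so the rates below do not show how often the tests call a clustered list. With uniform placement, the test of the piRNA domains called 5.5% of 200 lists, that of the autosome centres 3.5%, and the test per chromosome called at least 1 chromosome in 4.9% of 2000 lists. With a 2-fold higher density in the piRNA domains, 98% of 200 lists were called. For the score test, 3% of 200 lists with equal scores were called, and for the spacing test 2% of 50 uniform lists. The peaks named by position are the 10 with the lowest q and the strongest peak of each chromosome, a rule written before the data were examined.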

Results

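The series mapped where a tagged GEI-11 protein was bound in the genome of L4 larvae. The series title writes GEI-1, but the strain and sample labels give gei-11, which is used here. GEI-11, whose gene is now called snpc-4 (from general knowledge, as the gene table lists no older name), is a Myb-domain protein and a subunit of SNAPc, the complex that acts at promoters of small nuclear RNA genes and is also known from the domains of piRNA (21U-RNA) genes on chromosome IV. The gene table lists snpc-4 on chromosome I; whether a peak lies at this gene was not analysed here. The comparison made by the authors was ChIP DNA (2 samples) against input DNA (2 samples), and its outcome was a single combined list of 687 peaks. The values below describe that list and have no error between replicates.

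Binding regions were short and sparse. The 687 peaks had a median width of 331 bp (quartiles 252 and 439 bp), ranged from 2 to 3606 bp, did not overlap one another, and covered 267779 bp, or 0.268% of the 99735880 bp spanned on the 6 chromosomes. Strength varied over a wide range. The authors' q-values ran from 1.59e-240 to 0.00925 with a median of 0.000395, that is, a median −log10 q of 3.40 (quartiles 2.50 and 6.85). There were 126 peaks at a q of 1e-10 or less and 90 at 1e-20 or less. The 10 peaks shorter than 100 bp were all weak, with a −log10 q of at most 2.36.

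The 3 strongest peaks were on chromosome II. The lowest q (1.59e-240) belonged to the 1241 bp peak at chromosome II, 5543285 to 5544525, followed by the 1164 bp peak at II, 13834238 to 13835401 (q = 1.71e-240) and the 1278 bp peak at II, 14803642 to 14804919 (q = 6.1e-237). The fourth, at III, 10989208 to 10989968, had a q of 1.58e-168. Next came the strongest peak of chromosome X, at 14476438 to 14477739, with a q of 6.82e-151, and a peak at II, 15025429 to 15026340, with a q of 6.48e-150. The strongest peak of chromosome V, at 8500284 to 8500873, had a q of 2.1e-149, and a second peak on III, at 12250056 to 12250792, had a q of 1.46e-148. The strongest peak of chromosome IV, at 9510719 to 9512087, had a q of 1.35e-146 and lay between the piRNA domains, not in either of them. The tenth was at II, 14017730 to 14018666 (q = 2.01e-138). The strongest peak of chromosome I ranked 12 in the list, at 2084740 to 2085467 (728 bp, q = 4.89e-135). All positions are on WS180, and the q-values are the authors'.

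Peaks were unevenly shared among the chromosomes. The exact tests here and below treat peaks as independent, although neighbouring peaks clustered, so their p-values can be too small. Chromosome X held 172 peaks, 25.04% of the list (95% interval 21.8 to 28.5%), against 17.5% of the summed span, a ratio of 1.43 (adjusted p = 2.36e-06, exact binomial test). Chromosome IV held 154 peaks, 1.29 times the expected number (adjusted p = 0.0012, same exact test). Chromosome I had the fewest, 43 peaks, where 103.8 were expected from its span, a ratio of 0.414 (exact test, adjusted p = 7.11e-12). The numbers on II (110 peaks, ratio 1.05), III (86 peaks, ratio 0.907) and V (122 peaks, ratio 0.848) did not pass the exact test (adjusted p = 0.596, 0.417 and 0.0654). Peak density ran from 2.85 per Mb on I to 9.84 per Mb on X. The median −log10 q was highest on I, at 4.41, and lowest on X, at 3.07. Among the 343 peaks with the lowest q, the ratios were 1.20 for X and 1.25 for IV, and neither passed the exact test (adjusted p = 0.153 and 0.136), whereas that of I stayed low at 0.521 (adjusted p = 0.000477). Among the 126 peaks at a q of 1e-10 or less, a split chosen after the data had been seen, X fell below expectation (11 peaks, ratio 0.498, adjusted p = 0.0412, exact binomial test), and the ratios of I (0.946) and IV (1.05) did not pass the exact test (adjusted p = 0.913 for each).

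**Figure D1:**
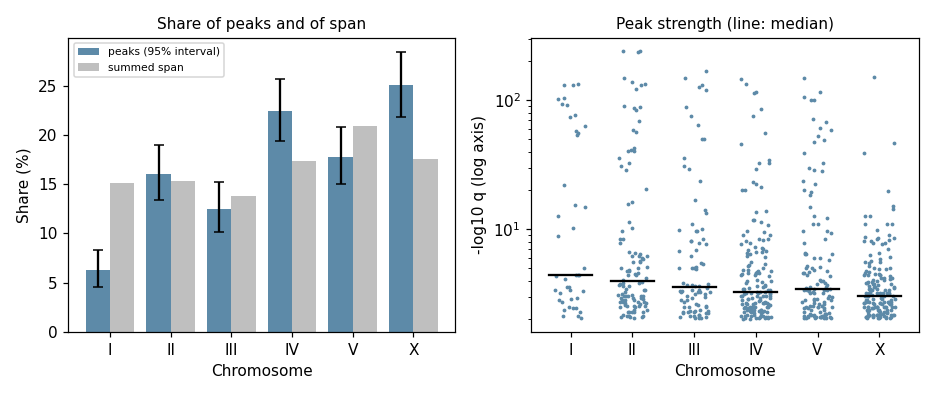
The left panel gives, for each chromosome, the percentage of the 687 peaks (blue bars, exact 95% intervals) beside its percentage of the summed span (grey bars). The right panel gives the −log10 q of each peak on a log axis, with a line at the median. X holds 25.04% of the peaks and has the lowest median, 3.07.

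Within chromosome IV, peaks were concentrated in the right piRNA domain. The question was whether the domains that hold piRNA genes, whose small RNAs guide the Argonaute PRG-1 in the germ line, carry more GEI-11 peaks than the rest of the chromosome. Of the 154 peaks on IV, 96 (62.3%, 95% interval 54.2 to 70.0%) lay in the 2 domains, which make up 34.7% of the span (p = 3.47e-12, exact binomial test). The right domain (13.5 to 17 Mb) held 73 peaks, 2.34 times its share of the span (p = 7.21e-14, same exact test). The left domain (4.5 to 7 Mb) held 23 peaks, 1.03 times its share (exact p = 0.819). A permutation test by rotating the peaks round the chromosome, which keeps their clustering, gave p = 0.0074 for both domains together, p = 0.0058 for the right one and p = 0.661 for the left one. Among the 343 peaks with the lowest q, the right domain still held 32 of the 74 on IV (43.2%, 2.13 times its share, exact p = 7.33e-06). It held 68 of the 131 peaks of IV at a q over 1e-10 (51.9%, exact p = 1.01e-15) and 5 of the 23 at a q of 1e-10 or less (21.7% against 20.3% of the span, exact p = 0.798), so the excess was not detected among the 23 strongest. The separate tests of the 2 domains and the split by q were chosen after the data had been seen.

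The 2 domains differed in their share of peaks at a q of 1e-10 or less, but no difference in median strength was detected. Of the peaks in the right domain, 6.85% were at a q of 1e-10 or less, against 30.4% in the left domain (odds ratio 0.168, adjusted p = 0.0396, Fisher's exact test) and 19.3% of the 591 peaks outside both (odds ratio 0.308, adjusted p = 0.0396, Fisher's exact test); this comparison was added after the data had been seen. The median −log10 q was 3.04 in the right domain and 4.37 in the left one, a difference of -1.34 (adjusted p = 0.152, permutation test). With both domains pooled, as planned, no difference in strength or width from the other peaks was detected. The pooled median −log10 q was 3.27, against 3.43 for the other peaks, a difference of -0.16 (95% interval -0.55 to 0.51, p = 0.524, permutation test). The pooled median width was 315.5 bp against 334 bp, a difference of -18.5 bp (95% interval -56 to 12 bp, p = 0.305, permutation test).

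The concentration at the right end was not particular to chromosome IV. The last 25% of the span held 107 of the 172 peaks on X (62.2%, 95% interval 54.5 to 69.5%), 63 of the 110 on II (57.3%, 47.5 to 66.7%), 78 of the 154 on IV (50.6%, 42.5 to 58.8%) and 33 of the 86 on III (38.4%, 28.1 to 49.5%). These shares exceeded 25% (adjusted p = 4.55e-24, 1.99e-12, 1.78e-11 and 0.00887, exact binomial tests), and those of I (30.2%) and V (26.2%) did not (adjusted p = 0.577 and 0.754). No test that keeps the clustering of peaks was run for these shares. On III, 19 of the 33 peaks lay between 11 and 12 Mb. The stretch from 12 to 13 Mb held 4 (6.24 expected) and the rest of III held 3 (4.82 expected). No difference was detected between the share on IV and that on II (odds ratio 0.766, adjusted p = 0.455, Fisher's exact test) or that on X (odds ratio 0.623, adjusted p = 0.131). In 1 Mb windows, X from 15 to 16 Mb held the most peaks, 39 where 9.84 were expected (adjusted p = 1.24e-11, exact binomial test over the 103 windows), with 31 from 16 to 17 Mb and 25 from 14 to 15 Mb. In the same exact test, chromosome II from 14 to 15 Mb held 26 peaks (7.21 expected, adjusted p = 4.44e-07), IV from 14 to 15 Mb held 25 (8.91 expected, adjusted p = 7.76e-05), III from 11 to 12 Mb held 19 (6.24 expected, adjusted p = 0.000222) and V from 14 to 15 Mb held 17 (5.84 expected, adjusted p = 0.00112). In all, 11 of the 103 windows passed the exact test above expectation and 5 below it, at a threshold of 0.05 on the adjusted p. The 5 were 10 to 11 and 11 to 12 Mb on IV, with 1 peak and none, and 6 to 7, 7 to 8 and 11 to 12 Mb on X, with 2, 1 and 2 peaks. The expected number of a window came from the peak density of its own chromosome, so equally empty windows elsewhere need not pass. Chromosome I from 7 to 8 Mb held no peak either, where 2.85 were expected (adjusted p = 0.370, same exact test).

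**Figure D2:**
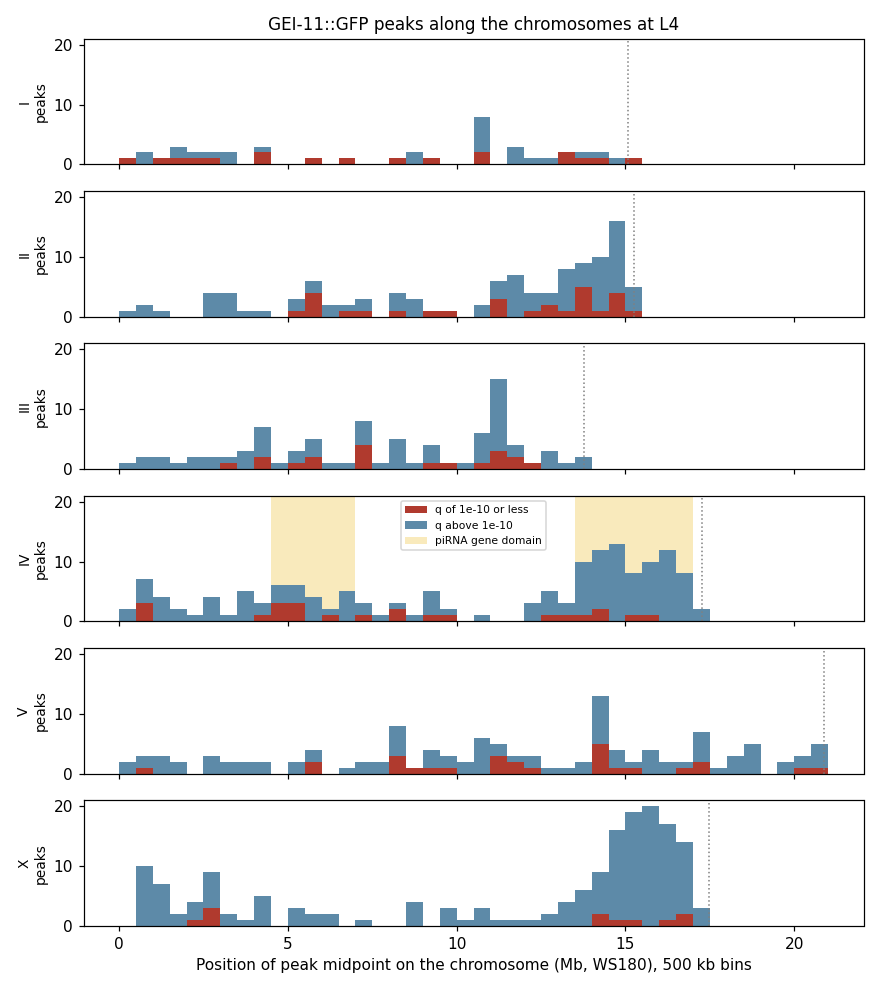
Number of peaks in 500 kb bins along each chromosome (WS180), by peak midpoint. Red marks peaks at a q of 1e-10 or less, blue the weaker ones, yellow the piRNA gene domains of chromosome IV, and the dotted line the end of the last peak. Peaks pile up at the right ends of II, IV and X, where the last 25% of the span holds 57.3%, 50.6% and 62.2% of the peaks.

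Autosomal peaks were scarcer in the central 50% of the spans than outside it. The part outside includes the right ends, where peaks piled up on II, III and IV, and the test does not separate left from right ends. It therefore does not show a contrast of the centres with both ends. The central 50% of the spans held 212 of the 515 autosomal peaks (41.2%, 95% interval 36.9 to 45.6%, p = 7.03e-05, exact binomial test). In exact tests per chromosome, the shares of II (31.8%, adjusted p = 0.000345) and IV (31.8%, adjusted p = 2.25e-05) passed, and those of I (39.5%, adjusted p = 0.266), III (47.7%, adjusted p = 0.747) and V (57.4%, adjusted p = 0.185) did not. The 5 autosomes differed in this share (p = 6.00e-05, permutation test over the 5, added after the data had been seen). This permutation treats peaks as independent and does not keep their clustering, so its p-value can be too small. Single pairs were not tested, and the 95% interval of I, which reaches 55.6%, also takes in the shares of II and IV. Without chromosome IV the share was 45.2% (exact p = 0.0734), and among the 343 peaks with the lowest q it was 46.1% (p = 0.224). The autosomal peaks at a q of 1e-10 or less lay on the other side of 50%, with 67 of 115 in the centres (58.3%, 95% interval 48.7 to 67.4%, exact p = 0.0928), so the scarcity was not seen among the strongest peaks. On X the central 50% held 27 of the 172 peaks (15.7%, adjusted exact p = 5.98e-20).

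Peaks also lay close to one another. In 100 cases neighbouring peak midpoints were within 5 kb, against a mean of 25.7 ± 4.68 (SD over 1000 random placements on the same chromosomes) and a highest random value of 50, a ratio of 3.89 (permutation p = 0.002, two-sided, the smallest value 1000 placements can give). In a test that was not planned, each peak was instead placed at random within its own 1 Mb window, so that the regional density was kept. The random mean was then 40.6 ± 5.50 (SD) and the ratio 2.46 (permutation p = 0.002). The ratio was 6.71 among the 343 peaks with the lowest q and 2.05 for neighbours within 20 kb (permutation p = 0.002 for each). After merging of peaks less than 1 kb apart, 61 cases remained, a ratio of 2.70 (permutation p = 0.002). Part of the closeness thus came from peaks less than 1 kb apart.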

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

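No paired analysis was possible because the deposited list combines both replicates of ChIP and input and gives no value per sample; for the same reason no replicate could be left out. Of 90 alternatives, 76 kept the side of the threshold and, where the value was called, its direction; 2 turned the direction of a called value. Both came from keeping only the 126 peaks at a q of 1e-10 or less, a split chosen after seeing the data: the ratio on X was 0.498 and the share in the autosome centres 58.3%, while the ratios on I (0.946) and IV (1.05) no longer passed. With only the 23 peaks of IV at that q, the share in both piRNA domains (52.2%) and that in the right one (21.7%) no longer passed. That in the left one (30.4%) did, with an exact binomial p of 0.039 that is not corrected for the number of such tests. Among the 343 peaks with the lowest q, the ratios of observed to expected peaks of 1.25 on IV and 1.20 on X, and the share of 46.1% in the autosome centres, no longer passed the test; fewer peaks were tested, but the values had also moved towards no difference, and the cause was not tested. Without chromosome IV the share in the autosome centres was 45.2% and no longer passed. With the number of protein-coding genes per chromosome in place of the span, an alternative chosen after seeing the data, chromosome V fell short of expectation (ratio 0.710, adjusted p = 1.32e-05, exact binomial test). The odds ratio of strong peaks on II, 1.67 and not called at a q of 1e-10, was called at 1e-20 (2.16) and for the 69 strongest peaks (2.39). The planned comparisons with annotated genes, gene lists and sequence were not run, because no annotation or sequence of WS180 was used here. Depth is unknown, the list stops at a q of 0.00925, and weaker binding cannot be assessed; ends of chromosomes past the last peak do not enter the spans.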

Other observations

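All comparisons by strength in this part, and the tests against weak peaks and piRNA gene number, were chosen after the data had been seen; those of occupied bins, peak width and tRNA gene number were chosen before their results were seen, except that the explanation tested by occupied bins was narrowed to stretches under 50 kb afterwards and that 10 and 20 width groups were added to the tertiles.

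Strong and weak peaks were spread differently over the genome. Of the 126 peaks at a q of 1e-10 or less, 11 (8.73%) were on X, against 161 of the 561 weaker peaks (28.7%), an odds ratio of 0.238 (adjusted p = 4.00e-06, Fisher's exact test over the 6 chromosomes). At a q of 1e-20 or less, 3 of 90 peaks were on X (odds ratio 0.0873, Fisher's exact test, adjusted p = 4.26e-08). Chromosome I, with the fewest peaks, had 18 of its 43 among the strong ones (odds ratio 3.57, Fisher's exact test, adjusted p = 0.000893). On the autosomes, 67 of 115 strong peaks (58.3%) and 145 of 400 weaker ones (36.3%) lay in the central 50% of the span (odds ratio 2.45, p = 3.85e-05, Fisher's exact test). Strong peaks were wider, with a median of 488 bp against 296 bp. The excess in the right piRNA domain of chromosome IV was seen among the 343 peaks with the lowest q, with 32 of the 74 on IV (43.2%, p = 7.33e-06, exact binomial test against 20.3%), and among the rest of the list, with 41 of 80 (51.2%, exact p = 7.42e-10). Of the 23 strong peaks of IV, 5 lay in the right domain (21.7%, exact p = 0.798) and 7 in the left one (30.4% against 14.5% of the span, p = 0.039, which is not corrected for the 6 tests of this kind).

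The pile-up of peaks at the right ends of II, IV and X was weighed against 3 explanations. If it came from weak peaks near the threshold, the 343 peaks with the lowest q should show 25% there: on II and X 63.2% of 136 such peaks were in the last 25% (95% interval 54.5 to 71.3%) and on IV 47.3% of 74 (95% interval 35.6 to 59.3%), which argues against this on all 3. At a q of 1e-10 or less the share was 56.4% of 39 peaks on II and X, but 26.1% of 23 on IV, against 55.0% of the 131 other peaks of IV (p = 0.0128, Fisher's exact test), so on IV the pile-up was not detected among the strongest peaks, while the 51 between this cut and the end of the 343 showed it (56.9%). Enriched stretches under 50 kb cut into many peaks would leave the occupied 50 kb bins even, but 48.8% of the 285 occupied bins of these chromosomes lay in the last 25% (95% interval 42.8 to 54.7%), which argues against such short stretches; stretches longer than 50 kb would fill several bins and stay open. If piRNA gene number caused the pile-ups on II and X as well, IV, with 95.8% of the 15363 piRNA genes in the gene table, should exceed II and X, with 109 and 162 of them. The odds of lying in the last 25% were not higher on IV (odds ratio 0.676 against II and X, 95% interval 0.455 to 1.00, p = 0.0552, Fisher's exact test). The odds ratio would be 3.08 if II and X held 25% there. This comparison cannot decide the question, because the high shares on II and X were known when it was chosen. A share within a chromosome also does not measure gene number, and the left piRNA domain lies outside the last 25% of IV. Chromosome V gives a contrast. It holds 202 piRNA genes, more than II or X. The last 25% of V held 26.2% of its peaks (95% interval 18.7 to 35.0%), against 57.3% on II and 62.2% on X. This argues against piRNA gene number per chromosome as the cause on II and X. The positions of these genes were not used, so an effect of piRNA genes near the right ends stays open there. An effect of piRNA gene number stays open for IV, where the left piRNA domain had no excess (1.03 times its share). A regional difference in coverage between ChIP and input, such as one from the scaling of the control, could not be examined without read counts and stays open, as does broad low-level binding of GEI-11 over the right piRNA domain.

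The scarcity of strong peaks on X could follow from narrow peaks there (median 300.5 bp), since width and strength rise together across peaks (Spearman rho 0.43, across peaks that are not independent replicates). With width held in tertiles, the pooled odds of a strong peak were lower on X than on the autosomes (Mantel-Haenszel odds ratio 0.29, 95% interval 0.153 to 0.548). This came from the widest tertile, from 389 bp, with 3 of 47 peaks strong on X against 90 of 183; in the middle one 8 of 54 were strong on X against 23 of 174 (odds ratio 1.14, p = 0.821, Fisher's exact test), and in the narrowest 0 of 71 against 2 of 158. With 20 width groups the pooled odds ratio was 0.275 (95% interval 0.141 to 0.537; 11 strong peaks on X where 26.0 were expected from width, p = 9.00e-05, permutation within groups), which argues against width as the whole cause. Lower enrichment on X and lower read depth on X would look alike in q-values and stay open, and no biological explanation was tested.

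As a hypothesis, the number of peaks per chromosome may follow the number of tRNA genes, of which X holds 276 of 612. Over the 6 chromosomes Pearson's r was 0.62 (exact permutation p = 0.217, adjusted p = 0.379 over 7 gene classes) and Spearman's rho 0.71 (exact permutation p = 0.136, adjusted p = 0.238); without II and X, r was 0.61. With 6 chromosomes this neither shows nor excludes a relation. No class passed the adjusted test; the lowest unadjusted p for Pearson's r was that of miRNA genes (r = 0.74, exact permutation p = 0.0833, adjusted p = 0.211; 0.49 without III and X), followed by other non-coding RNA genes (r = 0.74, exact permutation p = 0.0847) and snoRNA genes, with the opposite sign (r = -0.73, exact permutation p = 0.0903). For snRNA genes r was 0.14 (exact permutation p = 0.789; -0.85 without IV and V). For piRNA genes r was 0.42 (exact permutation p = 0.356), and 0.84 without IV and V. Their Spearman's rho was 0.77 (exact permutation p = 0.103, adjusted p = 0.238). Other non-coding RNA genes had the same rho, and both were above the rho of tRNA genes.

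The widest peak, 3606 bp at chromosome I, 15064020 to 15067625 (q = 4.98e-58), was the last peak on that chromosome. It was chosen for mention after its values were seen.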
